A study of Homo sapiens with 15 samples.

How the data were processed

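RNA sequencing of 15 HepG2 libraries was analysed from processed files. Per the labels, cells were transduced with lentivirus carrying a non-silencing hairpin (NS, 4 libraries), a hairpin against BRG1 (4), a hairpin against BRM (3) or both (4), selected with puromycin and harvested 5 days after transduction, and libraries were made from column-purified total RNA with a kit for mRNA.

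The deposited count table holds whole-number estimated counts per gene symbol for every library, not normalized between libraries. Kallisto, DESeq2 and GRCh38 are named in the submitters' processing notes, and their versions, their order, the transcript annotation and the strand setting are not given in the sources used here. Kallisto assigns reads to transcripts by compatibility and divides shared reads between similar transcripts by estimation, so values of paralogs and overlapping genes depend on that step. The authors' comparison tables, per the file headers, hold for each gene a mean normalized count, a log2 fold change with its standard error, a test score (the Wald statistic), a p-value and an adjusted p-value. The mean in the authors' tables is a signal equal to the mean of the deposited counts divided by size factors, with a largest relative difference of 0 from the recomputed value. The reference group of the authors' tables is not named in them, and the sign of SMARCA4 and SMARCA2 there was compared with the labels.

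Total counts per library ranged from 11500149 to 27187991. Of 35012 gene symbols, 33662 matched a gene name of GENCODE v29 on GRCh38, used for coordinates and gene types. Genes passing edgeR's filterByExpr on the group (14621) were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test (robust), with TMM factors and group means of all 15 libraries in 1 fit, so that all groups shared an estimate of the spread. Counts were used as deposited. The 7 contrasts were each knockdown against NS, the 3 differences between knockdowns, and the interaction (double minus BRG1 minus BRM plus NS on the log2 scale). Adjusted p-values are Benjamini-Hochberg values over the genes tested and genes under 0.05 are called. The standard error of a log2 fold change is its size divided by the square root of F. All tests are two-sided. CPM values use TMM-scaled totals, and log2 CPM for principal components and lists used a prior count of 2.

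The rule for named genes took, for each knockdown against NS, the 10 largest increases and 10 largest decreases among called genes with a mean of at least 2 CPM and every knockdown library on the same side of every NS library. It took 3 each way for the other pairwise contrasts, 5 each way for the interaction without the condition on sides, 4 per direction class among genes called in both single knockdowns, and up to 4 members per list by smallest adjusted p. SMARCA4 and SMARCA2 were always included. Some genes taken by this rule are not reported here. For a gene with 0 counts in a group, the fold is a bound against a floor of 3 counts over the group. For 1 to 3 counts the ratio has an exact binomial 95% interval. These cover counting error only, since reads without molecular identifiers are not independent molecules.

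Gene lists, 38 in all with 1095 entries, of which 1070 matched by symbol, 22 by an older symbol and 3 not at all, cover hepatocyte functions, metabolism, the cell cycle, stress and signalling programs, chromatin complexes and markers of other cell types. They were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01 and with a correlation estimated from the data, with Benjamini-Hochberg adjustment over the 38 lists in each comparison. A list counts as called at an adjusted p under 0.05 with the preset correlation. The count adjusted over the list alone repeats the adjustment over its measured members. Some lists share members, such as NR1H4 and PPARA, and the markers of other cell types include genes that HepG2 cells express, such as SPP1. Groups, tests, lists, the rule for named genes and the first alternatives were fixed before the data were examined.

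Every group has libraries numbered 1 and 2 and at least 1 numbered above 2, and the labels do not say what a number shares. The numbers were taken to pair samples where every pair's deviations from the group means correlated above 0.1, which shared sets alone may give. This held for BRG1 and NS (0.427 to 0.565), double and NS (0.179 to 0.454) and BRG1 and BRM (0.104 to 0.532). Chance overlap from shared controls was estimated from 20 simulated data sets of unchanged groups, again with the NS means of each replicate set and the spread within sets (added after the data were seen), and by splitting the NS libraries.

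The fits were tested on simulated data with 200 changed genes and no replicate sets. For the comparison of BRG1 with NS, edgeR recovered 4.48% of genes changed 1.5-fold, 31.3% of those changed 2-fold and 72.7% of those changed 4-fold. For BRM the shares were 1.49, 11.9 and 54.5%, and for the double knockdown 0, 16.4 and 65.2%. For the interaction they were 0, 1.49 and 33.3%. Over all comparisons the percentage of false calls was 0 to 9.88 for edgeR, 0 to 13.6 for edgeR with the replicate block, 0 to 9.41 for voom and 20.9 to 27.0 for DESeq2.

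Alternatives were DESeq2 1.42.0, limma-voom, RLE and upper quartile scaling, no filter, a stricter filter (1 CPM in 4 libraries), fits of only the groups compared, a replicate block, a test against a 1.5-fold change, and leaving out each library. A term for the replicate set, each set alone and library totals as the scale were added after the data were seen.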

Results

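RNA was sequenced from HepG2 cells, an established human liver cancer cell line, after lentiviral delivery of short hairpin RNAs against BRG1, against BRM or against both. BRG1 is the product of SMARCA4 and BRM the product of SMARCA2. They are the alternative ATPase subunits of the SWI/SNF (BAF) chromatin remodelling complexes. The 15 libraries comprised 4 from cells with a non-silencing hairpin (NS), 4 with the BRG1 hairpin, 3 with the BRM hairpin and 4 with both (double knockdown), all harvested 5 days after transduction. Total estimated counts per library ran from 11500149 to 22467399 in the NS group, 17291281 to 23734366 in the BRG1 group, 12550787 to 26998203 in the BRM group and 13885573 to 27187991 in the double group. The labels do not say that replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

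The libraries numbered 1 and 2 stood apart from those numbered 3 and 4 in every group. Transcripts encoded by mitochondrial DNA took 4.97 to 8.33% of the counts in the low-numbered libraries (1 and 2) and 1.33 to 3.55% in the high-numbered libraries (3 and 4), and 8134 genes differed between these sets. Values within each set (by set) are therefore given beside the pooled ones for called lists and some genes, low-numbered set first. Other genes carry a pooled value only, which may average unlike changes. The high-numbered set holds 1 BRM library. Within a group, libraries of the same set differed by a chi-square of 5.50 to 72.0 per degree of freedom and libraries of different sets by 107.9 to 246.9, so no pair agreed within sampling noise. This does not show separate cultures, and each library was counted as 1 replicate as labelled.

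**Figure D1:**
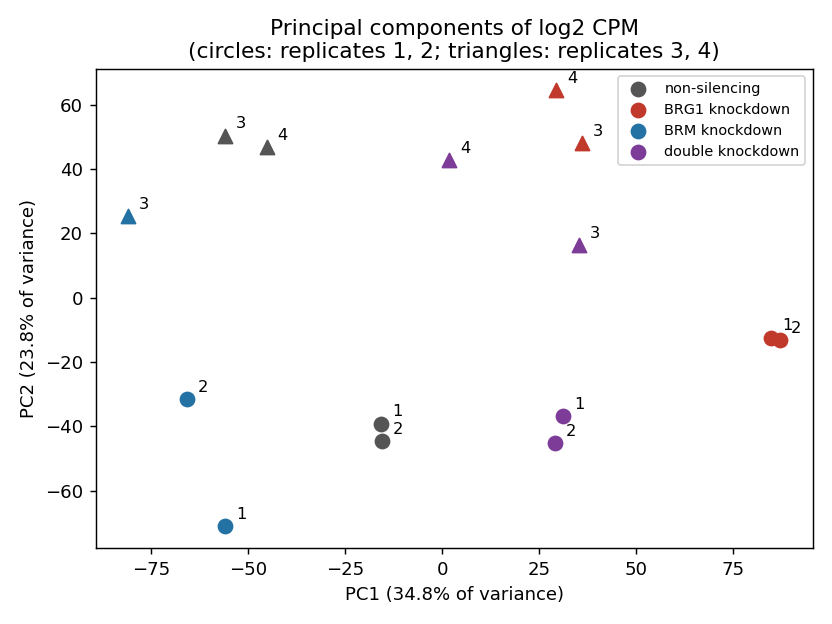
Scores of the 15 libraries on the leading principal components of log2 CPM, each point 1 library coloured by group with its replicate number beside it. The first component holds 34.8% of the variance and the second 23.8%, and libraries 1 and 2 of each group lie apart from libraries 3 and 4.

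SMARCA4 (GRCh38 chromosome 19, 10960825 to 11079426, plus strand, protein-coding) was measured over its whole transcript at 307 ± 6.99 CPM (counts scaled to library size, mean ± SD, n = 4) in the NS group, 27.8 ± 2.32 (n = 4) in the BRG1 group, 346 ± 86.7 (n = 3) in the BRM group and 46.2 ± 6.09 (n = 4) in the double group. Its libraries 1 to 4 held 312, 297, 310.3 and 310.1 CPM with the NS hairpin, 29.3, 29.002, 28.6 and 24.4 with the BRG1 hairpin, and 43.3, 52.0, 39.1 and 50.5 in the double knockdown. The 3 BRM libraries held 281, 312 and 444 CPM. SMARCA4 fell by 3.46 ± 0.17 on the log2 scale (estimate ± SE) after BRG1 knockdown (edgeR, adjusted p = 3.89e-08) and by 2.73 ± 0.17 in the double knockdown (adjusted p = 4.57e-07), whereas the change of 0.17 ± 0.17 after BRM knockdown did not pass (adjusted p = 0.584).

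SMARCA2 (chromosome 9, 1980290 to 2193624, plus strand, protein-coding) stood at 39.2 ± 4.05 CPM (SD, n = 4) in the NS group, 25.8 ± 3.64 (n = 4) in the BRG1 group, 4.38 ± 2.22 (n = 3) in the BRM group and 2.57 ± 0.299 (n = 4) in the double group. Per library it held 41.2, 33.2, 41.1 and 41.4 CPM with the NS hairpin, 28.1, 29.5, 21.6 and 23.9 with the BRG1 hairpin, 6.85, 2.55 and 3.73 with the BRM hairpin and 2.79, 2.23, 2.84 and 2.40 in the double knockdown. SMARCA2 fell by 3.18 ± 0.28 on the log2 scale after BRM knockdown (edgeR, adjusted p = 3.44e-05) and by 3.93 ± 0.26 in the double knockdown (adjusted p = 6.54e-07). After BRG1 knockdown it was lower in all 4 pairs of libraries by number, by −0.61 ± 0.23 (−0.37 and −0.90 within the sets), which did not pass in the fit used here (adjusted p = 0.0712) but did with the replicate number as a block (adjusted p = 0.0261), the set term, DESeq2 and voom.

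**Figure D2:**
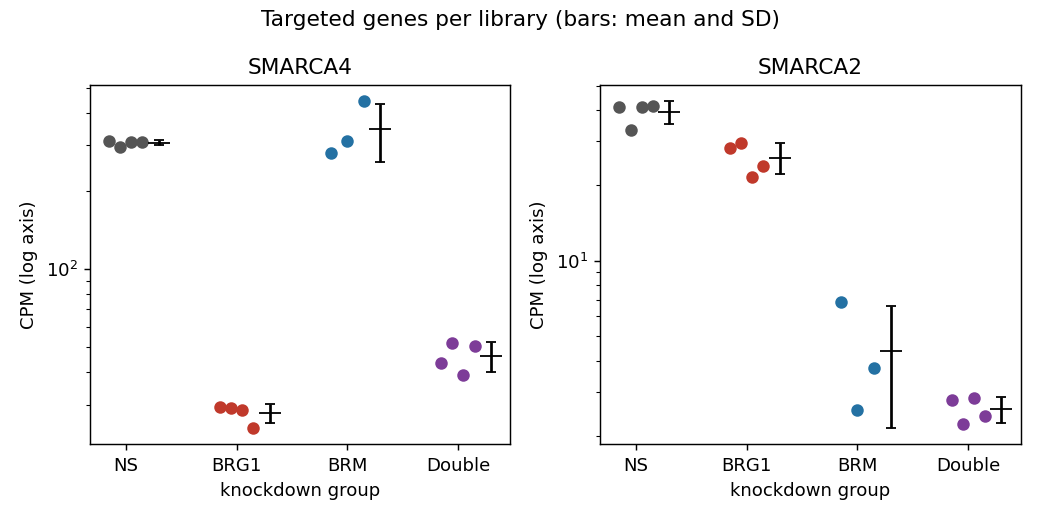
CPM of SMARCA4 and SMARCA2 on log axes in every library, with points for libraries, and the mean and SD of each group (n = 4, 4, 3 and 4). SMARCA4 averaged 307 CPM in the NS group and 27.8 CPM in the BRG1 group, and SMARCA2 averaged 39.2 CPM in the NS group and 4.38 CPM in the BRM group.

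The first comparison asked which transcripts change when BRG1 is depleted. After BRG1 knockdown 21 of 38 gene lists were called, those of liver secretion, liver metabolism and the cell cycle among the lower ones and those of immediate early genes, p53, YAP and TGFβ targets and mesenchymal genes higher. None of the 21 calls held with an estimated correlation between genes (adjusted p from 0.28 to 0.548). GFPT2 (chromosome 5, 180300690 to 180353387, minus strand), an enzyme that feeds the hexosamine pathway, rose from 0.928 to 70.8 ± 11.96 CPM (SD, n = 4), a log2 change of 6.27 ± 0.37 (SE, adjusted p = 3.2e-07, with 6.50 and 6.08 within the sets). BMP6 (chromosome 6, 7726797 to 7881422, plus strand), a ligand that controls hepcidin and iron balance, rose by 6.07 ± 0.59 (adjusted p = 1.35e-05). APOA5 (chromosome 11, 116789367 to 116792420, minus strand), an apolipoprotein that lowers plasma triglyceride, fell from 19.95 ± 4.30 to 1.28 ± 0.722 CPM (SD, n = 4 each), a log2 change of −3.95 ± 0.42 (adjusted p = 2.23e-05).

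In all, 1826 genes rose and 1458 fell after BRG1 knockdown (3284 at an edgeR adjusted p under 0.05), and 1936 of these changed at least 2-fold. The largest log2 increases also included FXYD5 at 5.40 ± 0.46, EMP1 at 5.35 ± 0.42, ARHGAP31 at 5.16 ± 0.61 (uncertain, NS at most 0.16 CPM) and NRG1 at 4.96 ± 0.61. KCTD14 (chromosome 11, 78015715 to 78046191, minus strand) had 0 counts in the NS group and 501 in the BRG1 group, at least 124-fold higher against a floor of 3 counts over the group (adjusted p = 0.00501). TSGA10IP (chromosome 11, 65945445 to 65959963, plus strand) had 2 NS counts and was higher by a ratio of 130 (95% counting interval 35.6 to 1075). The largest decreases also included GPHA2 at −4.49 ± 0.73, GSTA1 at −3.88 ± 0.45, AKR1B10 at −3.59 ± 0.55, ACSM2B at −3.47 ± 0.44, SMARCA4 itself and SERPINA4 at −3.30 ± 0.57. The rule requires every knockdown library on the same side of every NS library (8 of 8). KCTD14, GPHA2 and SERPINA4 overlap other annotated genes, and GSTA1, ACSM2B and AKR1B10 have close paralogs, so reads may be divided between copies and their values are uncertain.

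Lists of hepatocyte function were called lower. Of 32 measured plasma protein genes, 21 fell and 11 were not called (24 fell adjusted over the list alone). The median log2 change was −1.498 (−2.40 and −1.09 by set, camera adjusted p = 1.62e-13, adjusted p = 0.34 with estimated correlation). Examples were SERPINF1 at −2.59 ± 0.27, ITIH3 at −2.57 ± 0.35 and TTR, the thyroxine carrier, at −1.41 ± 0.20. In the complement list 15 of 22 fell and 1 rose (18 and 2 adjusted over the list alone). The median was −1.42 (−2.27 and −1.02 by set, adjusted p = 4.82e-08, adjusted p = 0.314 with estimated correlation). Examples were CD46 at −2.12 ± 0.20 and C4BPA at −2.15 ± 0.30. Of 21 apolipoprotein and lipoprotein genes, 11 fell and 1 rose (12 and 1 adjusted over the list alone). The median was −1.16 (−2.02 and −0.74 by set, adjusted p = 2.07e-06, adjusted p = 0.34 with estimated correlation). APOC3 fell by 2.51 ± 0.40 and the hepatic lipase LIPC by 1.37 ± 0.24, while ANGPTL4, an inhibitor of lipoprotein lipase, rose by 2.58 ± 0.35. Coagulation genes went both ways, with 11 of 25 lower and 5 higher (15 and 7 adjusted over the list alone). The median was −1.04 (−1.64 and −0.74 by set, adjusted p = 0.017, adjusted p = 0.472 with estimated correlation). F5, coagulation factor V, fell by 1.23 ± 0.15. Among those that rose were genes of the plasminogen activator system, PLAU at 3.40 ± 0.43 and its receptor PLAUR at 2.81 ± 0.25. Of 24 hepatocyte transcription factors 8 fell and 1 rose (9 and 1 adjusted over the list alone). The median was −0.73 (−0.92 and −0.63 by set, adjusted p = 0.000244, adjusted p = 0.314 with estimated correlation). The bile acid receptor NR1H4 fell by 2.73 ± 0.39, PROX1 by 1.02 ± 0.16 and FOXA1 by 0.89 ± 0.19. The coagulation call was lost without BRG1 library 1 or 2 (adjusted p = 0.0543 and 0.0644).

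Metabolic lists were called lower too. Xenobiotic metabolism had 12 of 26 genes lower (12 adjusted over the list alone). The median was −0.94 (−1.75 and −0.49 by set, adjusted p = 1.08e-06, adjusted p = 0.28 with estimated correlation). Examples were ALDH1A1 at −2.32 ± 0.23 and the fetal-type cytochrome CYP3A7 at −2.78 ± 0.34. Bile acid genes had 8 of 22 lower and 1 higher (8 and 1 adjusted over the list alone). The median was −0.79 (−0.92 and −0.48 by set, adjusted p = 0.00044, adjusted p = 0.28 with estimated correlation). Gluconeogenesis, urea cycle and amino acid genes had 11 of 28 lower and 1 higher (14 and 1 adjusted over the list alone). The median was −1.04 (−1.28 and −0.70 by set, adjusted p = 6.07e-05, adjusted p = 0.366 with estimated correlation). CPS1, the entry enzyme of the urea cycle, fell by 1.22 ± 0.14 and ASS1 by 1.68 ± 0.25, while NAGS rose by 3.21 ± 0.34. Cholesterol synthesis had 10 of 24 lower (12 adjusted over the list alone). The median was −1.02 (−1.10 and −1.11 by set, adjusted p = 0.000103, adjusted p = 0.538 with estimated correlation). Examples were HMGCS1 at −2.00 ± 0.47 and IDI1 at −1.13 ± 0.29. Fatty acid synthesis had 7 of 26 lower and 3 higher (9 and 3 adjusted over the list alone). The median was −0.62 (−0.46 and −0.78 by set, adjusted p = 0.00994, adjusted p = 0.548 with estimated correlation). Examples were GPAM at −2.63 ± 0.29 and ELOVL1 at 1.55 ± 0.33. Fatty acid oxidation had 9 of 26 lower and 1 higher (11 and 1 adjusted over the list alone). The median was −0.46 (−0.51 and −0.39 by set, adjusted p = 0.000411, adjusted p = 0.34 with estimated correlation). The fatty acid synthesis call was lost without BRG1 library 1, NS library 3 or NS library 4 (adjusted p = 0.0543, 0.0602 and 0.0668).

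Both cell cycle lists were called lower after BRG1 knockdown. Of 40 G1/S and replication genes, 20 fell (27 adjusted over the list alone). The median was −0.91 (−1.30 and −0.68 by set, adjusted p = 1.5e-12, adjusted p = 0.34 with estimated correlation). Examples were the replication clamp PCNA at −1.22 ± 0.19 and the primase subunit PRIM1 at −1.11 ± 0.18. Of 40 G2/M genes, 24 fell (31 adjusted over the list alone). The median was −1.01 (−1.41 and −0.83 by set, adjusted p = 1.05e-12, adjusted p = 0.366 with estimated correlation). Examples were TOP2A at −1.78 ± 0.25 and the proliferation marker MKI67 at −1.83 ± 0.33. Targets of p53 went the other way, with 11 of 31 higher and 1 lower (13 and 1 adjusted over the list alone). The median was 0.49 (0.57 and 0.33 by set, adjusted p = 0.00215, adjusted p = 0.366 with estimated correlation). PLK3 rose by 1.68 ± 0.21 and CDKN1A, the cyclin-dependent kinase inhibitor p21, by 1.21 ± 0.25. Genes of the ATF4 and unfolded protein response had 14 of 34 lower and 2 higher (16 and 3 adjusted over the list alone). The median was −0.69 (−0.64 and −0.75 by set, adjusted p = 0.000103, adjusted p = 0.366 with estimated correlation). Examples were ATF4 at −0.84 ± 0.16 and the chaperone HSP90B1 at −1.13 ± 0.23. NRF2 targets had 9 of 26 lower and 1 higher (10 and 2 adjusted over the list alone). The median was −0.46 (−0.77 and −0.34 by set, adjusted p = 0.000397, adjusted p = 0.366 with estimated correlation). An example was NQO1 at −2.40 ± 0.33. None of 53 ribosomal protein genes passed on its own in edgeR or voom (6 at an unadjusted p under 0.05, and 4 called by DESeq2), and their median was −0.18 with −0.47 and −0.06 within the sets (adjusted p = 0.00305, adjusted p = 0.548 with an estimated correlation, and adjusted p = 0.0584 without BRG1 library 2).

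The lists of immediate early genes, YAP targets, TGFβ targets and mesenchymal genes were called higher. Among 27 immediate early and heat shock genes, 16 rose and 2 fell (17 and 2 adjusted over the list alone). The median was 1.06 (1.05 and 0.66 by set, adjusted p = 3.31e-05, adjusted p = 0.28 with estimated correlation). Examples were FOSL1, a subunit of AP-1, at 2.62 ± 0.19 and KLF2 at 3.13 ± 0.31. Of 24 YAP targets, 12 rose (13 adjusted over the list alone). The median was 0.82 (1.02 and 0.71 by set, adjusted p = 0.000289, adjusted p = 0.397 with estimated correlation). Examples were MYOF at 4.003 ± 0.39 and the receptor tyrosine kinase AXL at 2.18 ± 0.29. Of 27 TGFβ targets, 9 rose and 1 fell (10 and 1 adjusted over the list alone). The median was 0.29 (0.31 and 0.56 by set, adjusted p = 0.00612, adjusted p = 0.366 with estimated correlation). Examples were LTBP2 at 3.38 ± 0.38 and TIMP1 at 3.11 ± 0.43. In the list of mesenchymal transition and extracellular matrix genes, 8 of 30 rose and 1 fell (11 and 1 adjusted over the list alone). The median was 0.39 (0.35 and 0.75 by set, adjusted p = 0.0136, adjusted p = 0.502 with estimated correlation). Examples were ITGA5, the fibronectin receptor subunit, at 4.25 ± 0.44 and CNN1 at 3.06 ± 0.35.

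Lists that were not called after BRG1 knockdown had medians of 0.23 for 25 SWI/SNF subunits, −0.02 for oncofetal genes, −0.33 for Wnt targets, −0.31 for interferon genes, −0.22 for NF-κB and inflammation genes, 0.13 for epithelial junction genes, −0.22 for hypoxia and glycolysis, 0.17 for metallothioneins and metal transport, −0.10 for oxidative phosphorylation, −0.07 for HOX and other Polycomb targets, −0.10 for Polycomb and related chromatin subunits and 0.62 for replication-dependent histones. Their camera adjusted p ran from 0.0839 for interferon genes to 0.922 for NF-κB genes. Mitochondrially encoded transcripts had a median of 0.02, with −0.20 and 0.87 within the sets. Markers of other cell types were not called either, with medians of 0.25 for 8 cholangiocyte, 0.17 for 5 stromal, −0.04 for 9 blood and endothelial and 0.96 for 4 neural genes (adjusted p = 0.936, 0.677, 0.758 and 0.303). Median, mean and test differed in sign only in lists that were not called, here the oncofetal and cholangiocyte lists.

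Within the sets, 5610 and 3784 genes passed, 2499 of them in both with the same sign and 32 with opposite signs, and the log2 changes of all tested genes had a correlation of 0.566 between the sets. Of the 3284 pooled calls, selected on the same libraries, 3282 had the same sign in both. With the replicate number as a block 5318 genes passed.

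The second comparison asked which transcripts change when BRM is depleted. After BRM knockdown 14 of 38 lists were called, 9 of liver secretion and metabolism, oxidative phosphorylation and p53 targets higher, and Wnt targets, Polycomb targets and G2/M genes lower. None of the 14 calls held with an estimated correlation (adjusted p from 0.177 to 0.94). GSTA1 (chromosome 6, 52791664 to 52803910, minus strand), a hepatic glutathione transferase, rose from 34.4 ± 15.1 (SD, n = 4) to 633 ± 164 CPM (n = 3), a log2 change of 4.20 ± 0.45 (SE, adjusted p = 7.56e-05), and its neighbour GSTA2 (52750089 to 52763569, minus strand) by 3.98 ± 0.45. G6PC (chromosome 17, 42900797 to 42913369, plus strand), the glucose-releasing phosphatase of gluconeogenesis, rose by 3.87 ± 0.62 (adjusted p = 0.00102). SPP1, which encodes the secreted phosphoprotein osteopontin (chromosome 4, 87975650 to 87983426, plus strand), fell from 656 ± 109 to 48.4 CPM, a log2 change of −3.76 ± 0.51 (adjusted p = 0.000354). PLA2G2A (chromosome 1, 19975431 to 19980416, minus strand), a secreted phospholipase, fell from 29.6 ± 14.7 to 0.46 CPM, a log2 change of −5.95 ± 0.49 (adjusted p = 2.22e-05).

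In all, 1120 genes rose and 915 fell after BRM knockdown (2035), and 1186 changed at least 2-fold. GBA3 (chromosome 4, 22692914 to 22819575, plus strand), annotated as a polymorphic pseudogene, rose by 6.60 ± 0.66 (uncertain, NS at most 0.194 CPM). PGLYRP2 rose by 5.07 ± 0.60, UROC1 by 4.48 ± 0.66 and KANK3 by 4.28 ± 0.41. The potassium channel gene KCNJ10 fell by 4.54 ± 0.56, the protease ADAMTS14 by 4.13 ± 0.98, perforin (PRF1) by 3.86 ± 0.59, the chemokine CCL20 by 3.82 ± 0.83 and ARSI by 3.62 ± 0.80. KLK6 had 3 counts in the BRM group, a ratio of 33.1 lower (95% counting interval 11.05 to 163). By the rule every BRM library lay on the same side of every NS library (7 of 7) for these genes. GSTA1 and GSTA2 share reads as near copies, KANK3 overlaps RPS28 on the opposite strand, and their values are uncertain. ADAMTS14, ARSI and CCL20 no longer passed without BRM library 2 (adjusted p = 0.0586, 0.0537 and 0.0504), nor ADAMTS14 with voom (adjusted p = 0.138) or in the high-numbered set alone (adjusted p = 0.0546).

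The fatty acid oxidation list was called higher. Of 26 genes 16 rose and 1 fell (19 and 1 adjusted over the list alone). The median was 0.86 (0.89 and 0.56 by set, camera adjusted p = 6.49e-08, adjusted p = 0.177 with estimated correlation). SLC25A20, the mitochondrial carnitine carrier, rose by 2.90 ± 0.27, CPT1A, the rate-limiting carnitine palmitoyltransferase, by 1.64 ± 0.23 and ACAA2 by 1.22 ± 0.15. Gluconeogenesis, urea cycle and amino acid genes had 9 of 28 higher (11 adjusted over the list alone). The median was 0.63 (0.83 and 0.60 by set, adjusted p = 0.000172, adjusted p = 0.702 with estimated correlation). Examples were BHMT at 3.42 ± 0.45 and GNMT at 2.61 ± 0.44. Cholesterol synthesis had 3 of 24 higher (5 adjusted over the list alone). The median was 0.99 (1.61 and 0.74 by set, adjusted p = 0.000172, adjusted p = 0.809 with estimated correlation). Examples were SC5D at 1.06 ± 0.24 and MSMO1 at 1.54 ± 0.39. Fatty acid synthesis had 7 of 26 higher and 1 lower (9 and 3 adjusted over the list alone). The median was 0.72 (1.05 and 0.35 by set, adjusted p = 0.0188, adjusted p = 0.809 with estimated correlation). Examples were LPIN1 at 1.28 ± 0.19 and DGAT2 at 1.38 ± 0.25. Oxidative phosphorylation had 6 of 42 higher and 2 lower (9 and 2 adjusted over the list alone). The median was 0.34 (0.31 and 0.23 by set, adjusted p = 0.0152, adjusted p = 0.809 with estimated correlation). Examples were SDHB at 1.03 ± 0.17 and NDUFB3 at −1.65 ± 0.21. Fatty acid synthesis was not called without NS library 1, NS library 2 or BRM library 3 (adjusted p = 0.0864, 0.0705 and 0.0962), nor oxidative phosphorylation without BRM library 2 or 3 (adjusted p = 0.156 and 0.0696).

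Liver secretory and detoxification lists other than complement were called higher. Of 32 plasma protein genes 11 rose and 3 fell (16 and 4 adjusted over the list alone). The median was 1.07 (1.08 and 0.93 by set, adjusted p = 0.00184, adjusted p = 0.809 with estimated correlation). FETUB rose by 2.94 ± 0.34 and KNG1 by 3.08 ± 0.48, while TTR fell by 1.55 ± 0.22. Of 21 apolipoprotein genes 3 rose and 1 fell (8 and 2 adjusted over the list alone). The median was 0.80 (0.63 and 0.95 by set, adjusted p = 0.0327, adjusted p = 0.809 with estimated correlation). Examples were APOE at 1.53 ± 0.24 and APOA2 at −1.25 ± 0.38. Coagulation genes had 8 of 25 higher and 3 lower (9 and 3 adjusted over the list alone). The median was 0.83 (0.78 and 0.57 by set, adjusted p = 0.0386, adjusted p = 0.809 with estimated correlation). Examples were factor X (F10) at 1.79 ± 0.27, fibrinogen beta (FGB) at 2.87 ± 0.63 and TFPI, the tissue factor pathway inhibitor, at −1.57 ± 0.20. Xenobiotic metabolism had 11 of 26 higher and 1 lower (11 and 2 adjusted over the list alone). The median was 0.97 (0.64 and 1.30 by set, adjusted p = 0.00332, adjusted p = 0.582 with estimated correlation). Examples were ADH4 at 3.69 ± 0.57 and ALDH1A1 at 1.42 ± 0.23. Bile acid genes had 6 of 22 higher (7 adjusted over the list alone). The median was 0.38, or 0.28 with 1 member without counts in a group placed at its bound (0.39 and 0.38 by set, adjusted p = 0.0267, adjusted p = 0.39 with estimated correlation). An example was the bile acid exporter subunit SLC51A at 2.27 ± 0.32. Of 22 complement genes 4 rose and 2 fell, with a median of 0.17 and a mean of −0.04 (adjusted p = 0.622). MBL2, the mannose-binding lectin, fell by 3.09 ± 0.69 and C1S rose by 1.13 ± 0.26. Hepatocyte transcription factors had 1 of 24 higher and 2 lower, with a median of 0.13 (adjusted p = 0.996). Apolipoprotein genes were not called without NS library 2 or BRM library 3 (adjusted p = 0.0522 and 0.0921), nor coagulation genes without NS library 1, BRM library 1, NS library 2 or BRM library 3 (adjusted p = 0.0626, 0.073, 0.0653 and 0.0696).

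The list of p53 targets was called higher after BRM knockdown too, with 15 of 31 higher (18 adjusted over the list alone). The median was 0.67 (0.69 and 0.68 by set, adjusted p = 2.14e-07, adjusted p = 0.201 with estimated correlation). Examples were TP53I3 at 2.03 ± 0.21 and BTG2 at 1.34 ± 0.20. Wnt targets were called lower, with 8 of 23 lower and 1 higher (9 and 1 adjusted over the list alone). The median was −0.36 (−0.47 and −0.44 by set, adjusted p = 0.00673, adjusted p = 0.177 with estimated correlation). Examples were the antagonist DKK1 at −2.13 ± 0.42 and the receptor LGR5 at −1.07 ± 0.22. HOX and other Polycomb targets had 4 of 17 lower (5 adjusted over the list alone). The median was −0.84 (−0.89 and −0.37 by set, adjusted p = 0.0102, adjusted p = 0.317 with estimated correlation). Examples were PAX8 at −1.03 ± 0.27 and IRX3 at −1.48 ± 0.40. Of 40 G2/M genes 1 fell, ECT2 at −0.82 ± 0.25, and 0 passed adjusted over the list alone in edgeR. The median was −0.29 (−0.13 and −0.56 by set, adjusted p = 0.0364, adjusted p = 0.94 with estimated correlation). The G2/M call was lost with the replicate block (adjusted p = 0.27), with the set term (adjusted p = 0.178) and without BRM library 2, NS library 3, BRM library 3 or NS library 4 (adjusted p = 0.365, 0.157, 0.0836 and 0.127), and the call of Polycomb targets without BRM library 3 (adjusted p = 0.0696) or a low count filter (adjusted p = 0.276). None of 40 G1/S genes passed in edgeR, DESeq2 or voom (4 at an unadjusted p under 0.05). The other lists were not called, with medians between −0.53 for NF-κB genes and 0.38 for replication-dependent histones, apart from the small marker lists of other cell types at −0.37 for cholangiocyte, 0.54 for stromal, 0.49 for blood and endothelial and −1.22 for neural genes (adjusted p = 0.533, 0.622, 0.622 and 0.262). Mitochondrially encoded transcripts had a median of 0.32, with −0.18 and 1.33 within the sets.

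Within the sets 4049 and 3084 genes passed, 1509 in both with the same sign and 25 with opposite signs, and the correlation across all tested genes between the sets was 0.405. Of the 2035 pooled calls 2032 had the same sign in both. Without BRM library 2, 959 genes passed, and 1002 fitting BRM and NS alone. With library totals as the scale, which shifts the median of all genes by −0.17, the split was 656 higher and 1255 lower. The majority turned in 2 of 13 settings and 10 of 15 fits without a library.

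The third comparison asked what happens when both ATPases are depleted. In the double knockdown 17 of 38 lists were called. Lower ones included 6 liver lists, oncofetal genes and Wnt targets, but not coagulation or the lists of lipid and amino acid metabolism, and immediate early genes and p53, YAP and TGFβ targets were higher. With an estimated correlation 2 of the 17 calls held, oncofetal genes and Wnt targets, and the others had adjusted p from 0.0534 to 0.748. BMP6 rose by 5.80 ± 0.59 (SE, n = 4 and 4, adjusted p = 1.56e-05) and the chemokine CCL5 (chromosome 17, 35871491 to 35880793, minus strand) by 4.92 ± 0.41 (adjusted p = 3.7e-06). AZGP1 (chromosome 7, 99966720 to 99976157, minus strand), a secreted lipid-mobilising glycoprotein, fell from 46.8 ± 8.74 to 1.84 ± 0.247 CPM (SD), a log2 change of −4.66 ± 0.22 (adjusted p = 2.63e-08). PLA2G2A fell by 5.73 ± 0.43 (adjusted p = 1.43e-06) and RELN, the secreted glycoprotein reelin (chromosome 7, 103471784 to 103989516, minus strand), by 4.38 ± 0.38.

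In all, 1718 genes rose and 1447 fell (3165), and 1807 changed at least 2-fold. ARHGAP31 rose by 5.89 ± 0.62 (uncertain, NS at most 0.16 CPM), PRSS22 by 5.36 ± 0.48 and KCNN4 by 4.96 ± 0.40. TSGA10IP was higher by a ratio of 140 (95% counting interval 38.4 to 1160). NFE2 fell by 5.04 ± 1.08, the acute phase protein SERPINA3 by 4.38 ± 1.04 and ODAM by 4.31 ± 0.43. SERPINA3 overlaps another annotated gene and its value is uncertain. Every double-knockdown library lay on the same side of every NS library (8 of 8) for these genes.

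Of 20 oncofetal genes 11 fell (12 fell and 1 rose adjusted over the list alone). The median was −0.65 (−0.58 and −0.75 by set, camera adjusted p = 0.000772, adjusted p = 0.0418 with estimated correlation). MEST fell by 1.41 ± 0.15 and GPC3, a marker of liver cancer, by 0.86 ± 0.19. Of 23 Wnt targets 11 fell and 1 rose (12 and 2 adjusted over the list alone). The median was −0.94 (−0.999 and −0.61 by set, adjusted p = 0.000772, adjusted p = 0.0418 with estimated correlation). LGR5 fell by 1.58 ± 0.21 and the Wnt deacylase NOTUM by 1.45 ± 0.26. With the replicate number as a block these calls held at the preset correlation (adjusted p = 0.00112 and 0.0012) and were lost with an estimated one (adjusted p = 0.146 for oncofetal genes and 0.263 for Wnt targets). Immediate early and heat shock genes had 15 of 27 higher (18 higher and 1 lower adjusted over the list alone). The median was 1.08 (1.03 and 1.16 by set, adjusted p = 1.27e-07, adjusted p = 0.0534 with estimated correlation). Examples were KLF2 at 4.73 ± 0.32 and JUNB at 2.63 ± 0.24. Targets of p53 had 18 of 31 higher (19 adjusted over the list alone). The median was 0.79 (0.67 and 0.83 by set, adjusted p = 1.13e-06, adjusted p = 0.156 with estimated correlation). An example was TP53I3 at 1.87 ± 0.20.

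Of 32 plasma protein genes 15 fell (15 adjusted over the list alone). The median was −0.89 (−0.69 and −1.14 by set, adjusted p = 1.5e-05, adjusted p = 0.649 with estimated correlation). An example was TTR at −2.99 ± 0.21. Complement had 11 of 22 lower and 1 higher (13 and 1 adjusted over the list alone). The median was −1.36 (−1.25 and −1.43 by set, adjusted p = 4.7e-06, adjusted p = 0.366 with estimated correlation). An example was MBL2 at −3.88 ± 0.64. Apolipoprotein genes had 7 of 21 lower and 3 higher (7 and 3 adjusted over the list alone). The median was −1.04 (−0.42 and −1.02 by set, adjusted p = 0.0159, adjusted p = 0.692 with estimated correlation). Examples were APOA4 at −2.50 ± 0.43 and ANGPTL4 at 4.56 ± 0.37. Xenobiotic metabolism had 11 of 26 lower (11 lower and 1 higher adjusted over the list alone). The median was −0.96 (−1.33 and −0.56 by set, adjusted p = 0.000331, adjusted p = 0.366 with estimated correlation). An example was UGT2B7 at −2.37 ± 0.24. Bile acid genes had 8 of 22 lower and 1 higher (9 and 1 adjusted over the list alone). The median was −0.65 (−0.71 and −0.68 by set, adjusted p = 0.00155, adjusted p = 0.156 with estimated correlation). An example was ABCB4, the phospholipid exporter, at −1.52 ± 0.19. Hepatocyte transcription factors had 7 of 24 lower and 1 higher (7 and 1 adjusted over the list alone). The median was −0.51 (−0.24 and −0.64 by set, adjusted p = 0.00393, adjusted p = 0.414 with estimated correlation). An example was PROX1 at −1.58 ± 0.16. The apolipoprotein call was lost without double library 3 (adjusted p = 0.0733).

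G1/S genes had 8 of 40 lower and 1 higher (8 and 1 adjusted over the list alone). The median was −0.38 (−0.29 and −0.55 by set, adjusted p = 0.00201, adjusted p = 0.738 with estimated correlation). G2/M genes had 3 of 40 lower (2 adjusted over the list alone). The median was −0.39 (−0.12 and −0.78 by set, adjusted p = 0.00155, adjusted p = 0.748 with estimated correlation). An example was MKI67 at −1.28 ± 0.33. YAP targets had 8 of 24 higher and 1 lower (10 and 1 adjusted over the list alone). The median was 0.69 (0.53 and 0.66 by set, adjusted p = 0.0147, adjusted p = 0.692 with estimated correlation). An example was MYOF at 2.41 ± 0.37. TGFβ targets had 9 of 27 higher and 1 lower (9 and 1 adjusted over the list alone). The median was 0.33 (0.10 and 0.99 by set, adjusted p = 0.00579, adjusted p = 0.526 with estimated correlation). ATF4 and unfolded protein response genes had 9 of 34 lower and 2 higher (10 and 3 adjusted over the list alone). The median was −0.43 (−0.07 and −0.76 by set, adjusted p = 0.0159, adjusted p = 0.692 with estimated correlation). An example was the chaperone HSPA5 at −1.21 ± 0.26. NRF2 targets had 7 of 26 lower and 1 higher (7 and 1 adjusted over the list alone). The median was −0.44 (−0.66 and −0.22 by set, adjusted p = 0.00564, adjusted p = 0.562 with estimated correlation). Examples were AKR1B10 at −4.20 ± 0.57 and the heme oxygenase HMOX1 at 2.78 ± 0.29. Ribosomal protein genes had 4 of 53 lower (1 adjusted over the list alone). The median was −0.18 (−0.18 and −0.28 by set, adjusted p = 0.00337, adjusted p = 0.692 with estimated correlation). The call of ATF4 and unfolded protein response genes was lost without NS library 4 (adjusted p = 0.142).

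Lists not called in the double knockdown included NF-κB genes, with 4 of 15 higher and 1 lower and a median of 0.51 (adjusted p = 0.0521), and metallothioneins and metal transport, with 3 of 11 higher and a median of 0.46 (adjusted p = 0.0573), among them MT1A at 4.17 ± 0.40, whose reads may be shared with its paralogs. The metabolic lists had medians of −0.10 for fatty acid oxidation, −0.44 for cholesterol synthesis, −0.50 for fatty acid synthesis, −0.56 for gluconeogenesis and amino acids and −0.34 for coagulation (adjusted p = 0.356, 0.665, 0.1, 0.1 and 0.665). Markers of cholangiocyte, stromal, blood and endothelial and neural cells had medians of 0.13, −0.26, −0.12 and 0.04 (adjusted p = 0.775, 0.827, 0.665 and 0.88), and mitochondrially encoded transcripts 0.05, with −0.11 and 0.86 within the sets.

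Within the sets 4244 and 5022 genes passed, 2513 in both with the same sign and 70 with opposite signs, with a correlation across all tested genes of 0.517. Of the 3165 pooled calls 3161 had the same sign in both, and with the replicate number as a block 5200 genes passed. The authors' deposited tables have 3987, 2775 and 3823 genes at an adjusted p under 0.05 for BRG1, BRM and both, among them 3277, 2029 and 3155 of the calls made here with the same sign.

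**Figure D3:**
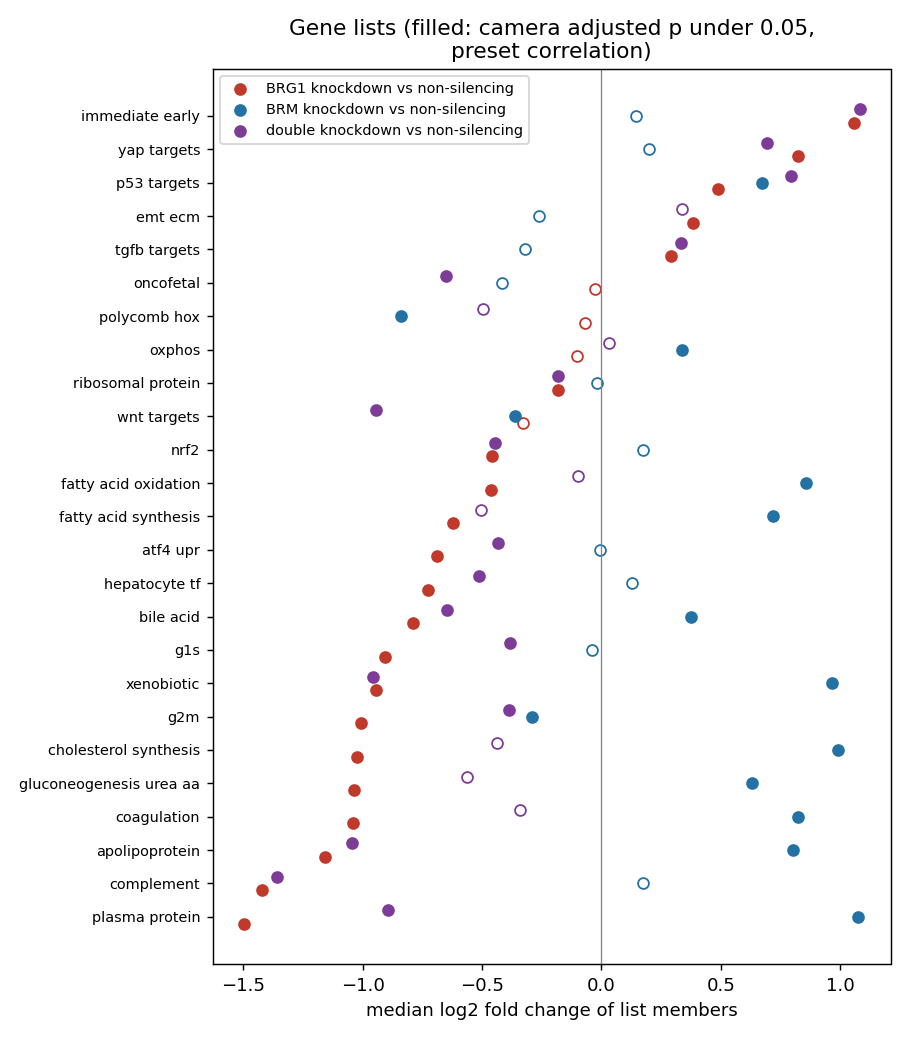
Median log2 fold change of each gene list called in at least 1 comparison with the NS group, with a point per comparison and filled points for a camera adjusted p under 0.05 at the preset correlation. Plasma protein genes lie at −1.498 after BRG1 knockdown, 1.07 after BRM knockdown and −0.89 in the double knockdown.

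The title of the series names cooperative and antagonistic regulation, so the single knockdowns were set against each other. Of the genes called in both, 311 moved in the same direction (166 up and 145 down) and 427 in opposite directions (205 higher after BRG1 and lower after BRM knockdown, and 222 the reverse). PTGES, a prostaglandin E synthase, rose in both (4.28 and 3.68, and 3.22 in the double knockdown), as did ANGPTL4 (2.58 ± 0.35 and 2.92 ± 0.37, and 4.56 ± 0.37) and PSTPIP2 (2.38 and 2.20, and 2.11). SPP1 fell in both (−3.02 and −3.76, and −3.98 in the double knockdown), as did PLA2G2A (−3.05 and −5.95, and −5.73), ODAM (−3.12 and −3.50, and −4.31) and HOXD1 (−2.87 and −3.33, and −3.49). GSTA1 fell after BRG1 and rose after BRM knockdown (−3.88 and 4.20, and −0.96 in the double knockdown), as did GSTA2 (−3.16 and 3.98, and −1.03) and the lectin gene LGALS2 (−2.32 and 2.75, and 1.07). MYBPH went the other way (3.75 and −3.43, and 0.29), with ADAMTS14 (2.61 and −4.13, and −0.80) and the Wnt modulator DKK3 (2.57 and −3.18, and −1.94).

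HOXD1 was not called after BRM knockdown without any of the BRM libraries or NS 3 or 4 (adjusted p from 0.0532 to 0.135), with voom or no filter (adjusted p = 0.0515 and 0.0666), nor after BRG1 knockdown without NS 4 or with only the groups compared (adjusted p = 0.0646 and 0.0643). After BRM knockdown PSTPIP2 was not called without BRM 2, NS 3 or NS 4 (adjusted p from 0.0523 to 0.11), or with only the groups compared (adjusted p = 0.0501), nor DKK3 without NS 1, BRM 2 or BRM 3 (0.0631 to 0.112), with voom or the high-numbered set alone (adjusted p = 0.126 and 0.103), and ADAMTS14 was not called after BRG1 knockdown without BRG1 2 (adjusted p = 0.0563).

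Independent lists of these sizes would share 231 genes in the same and 226 in opposite directions. Across genes, which are not independent replicates, the log2 changes of BRG1 and BRM knockdown had a correlation of 0.000577 and a covariance of 0.000468, against a simulated correlation of 0.462 and covariance of 0.0739 with the replicate sets kept, a covariance difference of −0.0734. BRG1 and double knockdown had a correlation of 0.701 and a covariance of 0.647 against 0.516 and 0.0737 (difference 0.573), and BRM and double knockdown 0.387 and 0.317 against 0.458 and 0.0745 (difference 0.242). Counting the difference between the sets as chance overstates the simulated covariances (0.115, 0.116 and 0.114). The share of genes with the same sign was 50.3% for BRG1 and BRM (64.2% simulated with the sets kept), 75.8% for BRG1 and double (67.1%) and 63.6% for BRM and double knockdown (64.2%). With separate NS libraries for each knockdown, in the 4 ways that give each knockdown an NS library of each set, 161, 104, 163 and 98 genes were called in opposite and 83, 74, 87 and 73 in the same direction, where independent lists would share 41.2 to 56.2 and 41.2 to 55.5. The covariance was then −0.0464, −0.000996, −0.0701 and −0.0226, each lower by less than the simulated 0.0739. Without BRM library 2, 153 genes were called in the same and 231 in opposite directions.

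**Figure D4:**
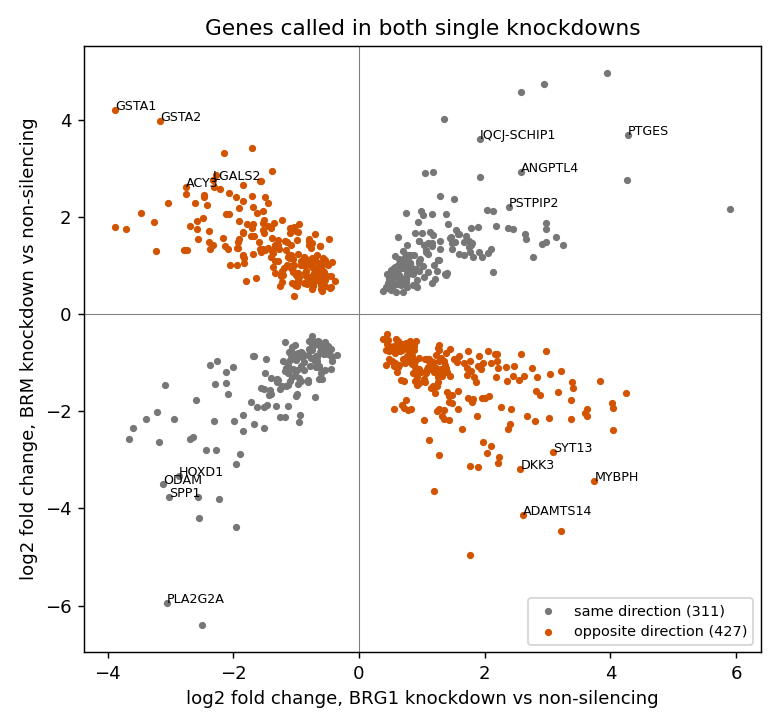
Log2 fold change after BRM knockdown (vertical axis) against that after BRG1 knockdown (horizontal axis), each point a gene called in both comparisons, coloured by direction. The plot holds 311 genes moving in the same direction and 427 moving in opposite directions.

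Of 1826 genes higher after BRG1 knockdown, 973 were also higher in the double knockdown and 32 lower, where independent lists would share 215 and 181, with a median of 1.18 in the single and 0.78 in the double knockdown. Of 1458 lower genes, 723 were also lower and 4 higher (independent 144 and 171, medians −1.10 and −0.72). Of 1120 genes higher after BRM knockdown, 386 were also higher and 79 lower (independent 132 and 111, medians 1.10 and 0.41), and of 915 lower genes 442 were also lower and 57 higher (independent 90.6 and 108, medians −1.13 and −0.63). The NS libraries are shared (same sign in 67.1% of simulated unchanged genes for BRG1 and 64.2% for BRM). Choosing genes by their single call shrinks the double medians in part, and weaker SMARCA4 depletion there was not separated.

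Compared directly, BRG1 and BRM knockdown differed in 4957 genes (2520 higher and 2437 lower after BRG1 knockdown). MYBPH was higher after BRG1 knockdown by 7.18 ± 0.64 (SE, n = 4 and 3, adjusted p = 2.06e-06), GFPT2 by 6.77 ± 0.44 and ADAMTS14 by 6.74 ± 1.02. GSTA1 was lower by a log2 change of −8.09 ± 0.54 (adjusted p = 3.41e-07), GSTA2 of −7.14 ± 0.53 and PGLYRP2, a peptidoglycan amidase secreted by the liver, of −6.43 ± 0.65. Within the sets 7235 and 4433 genes passed (3911 in both with the same sign and 4 with opposite signs, correlation across all tested genes 0.767), and 4955 of the pooled calls had the same sign in both. With library totals as the scale, which shifts the median of all genes by 0.21, the split was 3269 higher and 1746 lower.

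Adding BRM depletion to BRG1 depletion changed 1582 genes, 600 higher and 982 lower in the double than in the BRG1 knockdown. GBA3 was higher by 4.03 ± 0.56 (SE, n = 4 and 4, adjusted p = 0.000529), NPTX1 by 3.84 ± 0.69 and LGALS2 by 3.39 ± 0.41, and the kallikrein KLK6 was lower at −5.43 ± 0.68 (adjusted p = 0.000267), DPYSL3 at −5.10 ± 1.06 and the cartilage matrix gene COMP at −4.95 ± 1.12, which voom did not call (adjusted p = 0.0776). Within the sets 3967 and 1634 genes passed (1087 in both with the same sign and 18 with opposite signs, correlation 0.484), and 1581 of the pooled calls had the same sign in both. The count fell to 934 without double library 2.

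Adding BRG1 depletion to BRM depletion changed 2787 genes, 1363 higher and 1424 lower in the double than in the BRM knockdown. The serine protease gene PRSS22 was higher by a log2 change of 6.79 ± 0.61 (SE, n = 4 and 3, adjusted p = 6.98e-06) and KCNN4 by 6.27 ± 0.50. GSTA1 was lower at −5.17 ± 0.47 (adjusted p = 8.08e-06), GSTA2 at −5.02 ± 0.47 and NYNRIN at −4.93 ± 0.72. Within the sets 4507 and 3408 genes passed (2672 in both with the same sign and 1 with opposite signs, correlation 0.697), and 2786 of the pooled calls had the same sign in both. With library totals as the scale, which shifts the median of all genes by 0.22, the split was 2064 higher and 959 lower.

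The last comparison tested each gene for a departure of the double knockdown from the sum of the single effects (log2 scale). In all, 73 departed (15 above and 58 below), and the weaker SMARCA4 depletion was not separated. MSN, the membrane linker moesin (chromosome X, 65588377 to 65741931, plus strand), changed by 3.85 and 0.71 after BRG1 and BRM knockdown and −0.22 in the double knockdown, a departure of −4.78 ± 0.63 (SE, adjusted p = 0.00229, with −5.24 and −4.33 within the sets). EGFR, the epidermal growth factor receptor (chromosome 7, 55019021 to 55211628, plus strand), averaged 39.96 CPM in the NS, 218 in the BRG1, 135 in the BRM and 72.9 in the double group, a departure of −3.33 ± 0.40 (adjusted p = 0.00175, with −3.69 and −2.75 within the sets). BIRC3, an inhibitor of apoptosis and NF-κB target (chromosome 11, 102317450 to 102339403, plus strand), changed by 1.28, −1.15 and 3.37, a departure of 3.24 ± 0.54 (adjusted p = 0.0124, with 3.05 and 3.73 within the sets). CYP19A1, aromatase (chromosome 15, 51208057 to 51338610, minus strand), changed by −0.70, 2.77 and −0.73, a departure of −2.80 ± 0.40 (adjusted p = 0.00452). PTGES departed by −4.73 ± 0.72 and FETUB by −3.28 ± 0.49. SMPDL3B departed by 3.75 ± 0.53, CRABP2 by 3.36 ± 0.67, PLA2G2A by 3.28 ± 0.60 and LPAR6 by 2.51 ± 0.46. PLA2G2A could hardly fall further from at most 0.55 CPM in BRM libraries. Leaving out any library but double 4 ended the CRABP2 call (adjusted p from 0.0541 to 0.0919). PLA2G2A was lost without BRG1 1 or 2, BRM 2 or 3, or double 3 or 4 (0.0506 to 0.0659) and LPAR6 without BRM 2, BRG1 3 or NS 4 (0.0558 to 0.0623). Voom did not call CRABP2 or PLA2G2A (adjusted p = 0.0842 and 0.149), and the high-numbered set alone did not call SMPDL3B, CRABP2 or LPAR6 (0.072, 0.185 and 0.0561).

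Of the lists, NF-κB and inflammation genes lay above the sum, with 2 of 15 called (4 adjusted over the list alone). The median departure was 0.68 (0.81 and 0.70 by set, camera adjusted p = 6.2e-06, adjusted p = 0.203 with estimated correlation). The genes called were BIRC3 and TNFAIP3, a deubiquitinase that limits NF-κB, at 1.96 ± 0.32. Cell cycle lists also lay above the sum although none of their 40 and 40 members passed alone in edgeR or voom (8 G1/S and 17 G2/M genes at an unadjusted p under 0.05, and 2 and 3 called by DESeq2). The median departure of G1/S genes was 0.53 with 1.01 and 0.25 within the sets (adjusted p = 1.01e-08, adjusted p = 0.529 with estimated correlation) and that of G2/M genes 0.78 with 1.34 and 0.57 (adjusted p = 3.9e-14, adjusted p = 0.505 with estimated correlation). Fatty acid oxidation lay below the sum, with 3 of 26 called (4 adjusted over the list alone). The median was −0.36 (−0.31 and −0.45 by set, adjusted p = 0.000304, adjusted p = 0.491 with estimated correlation). Examples were ACSL1, an acyl-CoA synthetase, at −2.16 ± 0.24 and SLC25A20 at −1.76 ± 0.36. Targets of p53 had 1 of 31 called, PLK2 at −1.87 ± 0.32 (4 adjusted over the list alone). The median was −0.42 (−0.68 and −0.13 by set, adjusted p = 0.00171, adjusted p = 0.505 with estimated correlation). Bile acid genes had 1 of 22 called, SLC51A at −2.72 ± 0.44 (5 adjusted over the list alone). The median was −0.29 (−0.23 and −0.50 by set, adjusted p = 0.0408, adjusted p = 0.491 with estimated correlation).

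YAP targets had 1 of 24 called, NT5E at −1.73 ± 0.33 (1 lower and 1 higher adjusted over the list alone). The median was −0.44 (−0.73 and 0.11 by set, adjusted p = 0.0437, adjusted p = 0.897 with estimated correlation). No xenobiotic, interferon or metallothionein gene passed alone in edgeR or voom (9, 7 and 2 at an unadjusted p under 0.05, and 3, 0 and 1 called by DESeq2). Adjusted over the list alone, 3 xenobiotic genes lay below and 2 metallothionein genes above the sum. Median departures were −0.80 for 26 xenobiotic genes with −0.18 and −0.99 within the sets (adjusted p = 0.00862, adjusted p = 0.529 with estimated correlation), 0.34 for 35 interferon genes with 0.31 and 0.19 (adjusted p = 0.0327, adjusted p = 0.491 with estimated correlation) and 0.20 for 11 metallothionein and metal transport genes with 0.77 and −0.21 (adjusted p = 0.0437, adjusted p = 0.781 with estimated correlation). With the replicate block the calls of YAP targets, interferon genes and metallothioneins were lost (adjusted p = 0.3, 0.0867 and 0.0519). With the set term those of YAP targets, xenobiotic, bile acid, interferon and metallothionein genes were lost (adjusted p = 0.261, 0.0558, 0.066, 0.072 and 0.0819), and with RLE scaling that of metallothioneins (adjusted p = 0.0589). YAP targets were not called without BRG1 1 or 2, BRM 1 or 2, NS 3 or 4, or double 4 (adjusted p from 0.0797 to 0.188), metallothioneins without any of these or double 3 (0.0859 to 0.274) and interferon genes without BRM 1, BRG1 2 or double 4 (0.0564 to 0.177). Bile acid genes were not called without any of the BRG1 libraries, BRM 1 or double 3 (0.0513 to 0.327), and xenobiotic genes without BRM 1 (adjusted p = 0.0578).

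The pooled interaction fit has little power, since 1.49% of simulated 2-fold and 33.3% of 4-fold departures were recovered. Within the sets 1595 and 246 genes passed, 116 of them in both, with a correlation of the departures across all tested genes of 0.214. All 73 pooled calls, selected on the same libraries, had the same sign in both. The count was 38 without BRM library 2, 166 without BRM 1, 633 with the replicate block and 1061 with the set term. The split was 24 above and 50 below with upper quartile scaling. With library totals it was 41 and 34 (median of all genes shifted by 0.19).

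**Figure D5:**
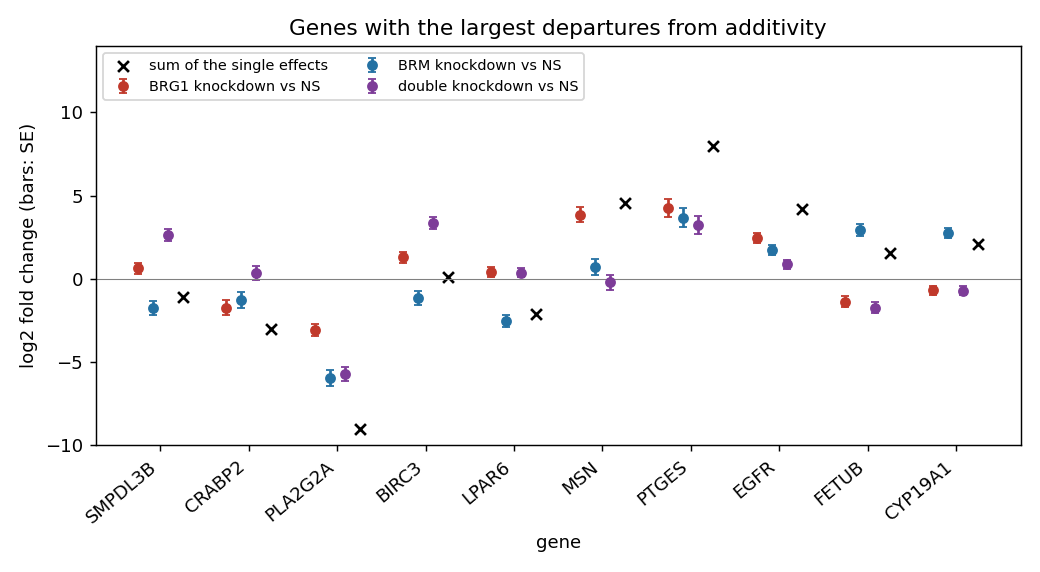
Log2 fold change against the NS group, with SE bars, of the 10 genes with the largest departures from the sum of the single effects, for BRG1, BRM and double knockdown, with a cross at that sum. MSN lies at −0.22 in the double knockdown against 3.85 and 0.71 in the singles, and BIRC3 at 3.37 against 1.28 and −1.15.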

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

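The tests on the replicate sets were written before their results were seen, except the removal of the trend of length and GC content. All tests of the cell cycle pattern, and for the opposite lists the tests within the sets and of scaling, were chosen only after the result was seen.

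Among 79 items, the named genes and measures of whole libraries, tested for a library far from the other 3 of its group, 17 of 237 groups had 1, where chance gives about 1 in 20 groups. The gap to the nearest library, as a share of the group's range, was 0.86 for KCTD14 in double library 2 (lowest), 1 for TSGA10IP in NS library 1 (highest), 0.912 for ARHGAP31 in NS library 3 (lowest), 0.895 for APOA5 in NS library 3 (highest), 0.946 for APOA5 in double library 4 (highest) and 0.835 for GSTA1 in double library 4 (highest). It was 0.899 for SMARCA4 in NS library 2 (lowest), 0.864 for SMARCA4 in BRG1 library 4 (lowest) and 0.971 for SMARCA2 in NS library 2 (lowest). It was 0.899 for SERPINA4 and for PGLYRP2 in double library 4 (highest), 0.882 for ADAMTS14 in double library 3 (highest), 0.905 for AZGP1 in double library 1 (lowest), 0.897 for NPTX1 in double library 4 (lowest), 0.921 for NYNRIN in NS library 3 (lowest), 0.858 for PTGES in NS library 4 (lowest) and 0.911 for ANGPTL4 in double library 4 (highest). Double library 4 accounts for 6 of them.

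The BRG1 effect differed with and without BRM knockdown for 73 genes (interaction test). The log2 difference was 3.75 for SMPDL3B, 3.36 for CRABP2, 3.28 for PLA2G2A (low counts), 3.24 for BIRC3 and 2.51 for LPAR6. It was −4.78 for MSN, −4.73 for PTGES, −3.33 for EGFR, −3.28 for FETUB and −2.80 for CYP19A1. Of 100 splits of the 15 libraries, 7 gave as many genes, the real one included, and the highest other gave 2259. Such splits can mix BRG1 and BRM effects into the interaction, so they do not decide on the count of 73.

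The separation of libraries 1 and 2 from libraries 3 and 4 covers 8134 genes. Depth as the cause is argued against, since 7779 genes differed with every library thinned to 11500149 counts, and so is a few abundant genes, since 8060 differed without 29 mitochondrially encoded or most abundant genes. Transcript length and GC content accounted for 15.7% of the variance of the difference across genes, which leaves a partial role open, but 6866 genes still differed with that trend removed from every library, which argues against it as the whole cause. Library or sequencing batches and separate rounds of culture may underlie the rest and cannot be separated here, and no biological explanation was tested because the labels give none.

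The opposite movement of 9 liver and metabolic lists, lower after BRG1 and higher after BRM knockdown, covers plasma proteins, apolipoproteins, coagulation, xenobiotic metabolism, bile acids, cholesterol synthesis, fatty acid synthesis, fatty acid oxidation and gluconeogenesis with amino acids. Complement and hepatocyte transcription factors, lower after BRG1 knockdown, were not called after BRM knockdown (adjusted p = 0.622 and 0.996), and with an estimated correlation none of the 9 was called in either comparison (adjusted p from 0.28 to 0.548 for BRG1 and 0.177 to 0.809 for BRM). All 9 had opposite medians in libraries 1 and 2 alone (and in 3 and 4, with 1 BRM library). This argues against an unequal make-up of the replicate sets. Scaling moves all genes alike, and their median lay within 0.14 of 0 in both comparisons under 4 scalings. The lists lay at −0.446 or lower and 0.187 or higher with TMM or library totals, which argues against scaling as the whole cause. Separate NS libraries left 9 opposite in each of 4 balanced splits, which does not decide, since NS libraries in common move both comparisons the same way. Off-target effects of the hairpins and an opposing role of BRG1 and BRM remain open, and the count of lists called in each comparison did not exceed what other splits of the libraries give.

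Cell cycle lists fell less in the double knockdown than the sum of the single effects. With BRM also depleted, the BRG1 effect on cell cycle genes kept 0.168 of its size in libraries 1 and 2. Other lowered genes (1705) kept 0.724 (difference −0.556). In libraries 3 and 4 it was 0.48 against 1.25 (2411 genes, difference −0.775). This argues against weaker SMARCA4 depletion only if it acts on all genes alike, which was not tested. The replicate sets as the cause stay open, since the adjusted p of at most 0.023 within each set became 0.547 to 0.775 with an estimated correlation, and libraries 3 and 4, with the weakest p, hold 1 BRM library. That the cell cycle response to BRG1 loss may depend on BRM is a hypothesis found and tested on the same data, and differences between cultures remain open.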

How the results depend on the processing

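The term for the replicate set, each set alone, library totals and the list tests that combine an estimated correlation with a block or set term were chosen after the data were seen, and the other settings were planned. No call of a named gene or list reversed under the settings run, but in the order below the share of higher calls ran from 49.8 to 60.7%, 34.3 to 57.2%, 48.2 to 57.7%, 25.9 to 46.4%, 47.0 to 68.3%, 49.5 to 65.2% and 12.9 to 54.7% over all settings. The majority direction turned in 1, 2, 5, 0, 2 and 4 of 13 settings (1 of 12 for the interaction) and in 2, 10, 8, 0, 4, 0 and 0 of 15 fits without a library. Interaction medians of YAP targets and metallothioneins differ in sign between sets. Counts of called genes follow in the order BRG1, BRM and double against NS, double against BRG1, double against BRM, BRG1 against BRM and the interaction, with genes called in both singles in the same and opposite direction last. Settings not printed for a result kept it within 1.5 times. DESeq2 called 453 genes for the interaction and 492 genes in the same direction, with a self-test share of false calls above that of edgeR. Without a filter, which tests more genes, 284 genes were called in opposite directions. Fits of only the groups compared gave 1002 genes for BRM (3055 for BRG1, 3087 for double) and 151 and 240 in both singles. The replicate block gave 5318, 4153, 5200, 3259, 5302 and 633 genes (7219 for BRG1 against BRM) and 775 and 1074 in both singles. Testing against a 1.5-fold change gave 1327, 570, 1225, 441, 1140, 2699 and 31, and 52 and 77. The set term gave 5720, 4684, 5646, 3728, 5718, 7659 and 1061, and 978 and 1212. Libraries 1 and 2 alone gave 5645, 4064, 3981, 4520 and 1619 (BRG1, BRM, double against BRG1, double against BRM and interaction), and 903 and 1164. Libraries 3 and 4 alone gave 3061 for BRM, 5045 for double and 243 for the interaction, and 821 in the same direction. These fits filter the genes anew within each set. With separate controls the balanced splits gave 161, 104, 163 and 98 genes in opposite and 83, 74, 87 and 73 in the same direction. Unbalanced ones (libraries 1 and 2 against 3 and 4) gave 530 and 447, and 178 and 181. The cause of these moves was not tested.

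With an estimated correlation 0 lists were called for BRG1, 0 for BRM, 2 for double and 0 for the interaction. The set term gave 5 lists for the interaction. With the set term and an estimated correlation 0, 0, 0 and 1 lists were called, and with the block and an estimated correlation 0, 0, 0 and 1, the list in both being NF-κB genes for the interaction (adjusted p = 0.022 and 0.0492).

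Leaving out a library in turn gave 2384 to 3454 genes for BRG1, 959 to 2063 for BRM (959 without BRM 2), 2316 to 3325 for double, 934 to 1714 for double against BRG1 (1038, 1014, 946 and 934 without BRG1 1, BRG1 2, double 1 and double 2), 1951 to 2799 for double against BRM and 3929 to 4990 for BRG1 against BRM. The interaction ran from 38 to 166 (44 without BRG1 1, 166 without BRM 1, 43 without double 1, 40 without BRG1 2, 38 without BRM 2, 41 without double 2, 43 without NS 3, 44 without BRG1 3 and 48 without NS 4). Genes in both singles ran from 153 to 372 in the same direction (153 without BRM 2, 198 without NS 3 and 200 without NS 4) and 231 to 406 in opposite directions (231 without BRM 2 and 283 without NS 3). Lists ran from 19 to 22 for BRG1, 8 to 14 for BRM (8 without BRM 3), 16 to 20 for double and 6 to 13 for the interaction (6 without BRM 1). Where BRM keeps 2 libraries, or 1 among libraries 3 and 4, they are assumed to vary like the other groups.

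Of 117 results for named genes, those no longer called numbered 6 with voom, 8 against a 1.5-fold change (among them HOXD1, PSTPIP2, DKK3, CRABP2, PLA2G2A and LPAR6), 1 without a filter, 1 with upper quartile scaling, 6 in libraries 3 and 4 alone and 0 with DESeq2, RLE, library totals, the block or the set term. Leaving out a library lost 46 of 1755. Of 62 list calls, 60 were lost with an estimated correlation, 4 with the block, 6 with the set term and 49 of 930 on leaving out a library. The replicate block ended no call of a named gene, and added that of SMARCA2 after BRG1 knockdown. BRM and NS (lowest correlation of deviations 0.0733), double and BRG1 (0.0578) and double and BRM (0.0133) share only a number, and 8 of 15 libraries correlated best with a library of their own number in another group and 15 with 1 of their own set. In simulation, 1.49% of 2-fold interaction departures over all tested genes were recovered.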

Other observations

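The comparison of the replicate sets was chosen after the data were seen, and the splits of the libraries were planned.

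Libraries 3 and 4 differed from libraries 1 and 2 across groups, with 3991 genes higher and 4143 lower. Cholesterol synthesis genes were higher in libraries 3 and 4, 22 of 24 with a median log2 difference of 1.15 (camera adjusted p = 1.71e-07). Fatty acid synthesis had 15 of 26 higher (median 0.50, adjusted p = 0.0011), hypoxia and glycolysis 20 of 32 higher and 4 lower (0.73, adjusted p = 0.0011), gluconeogenesis and amino acids 17 of 28 higher and 1 lower (0.59, adjusted p = 0.00241) and ATF4 and unfolded protein response genes 20 of 34 higher and 1 lower (0.43, adjusted p = 0.00182). G1/S genes had 21 of 40 higher and 2 lower (0.38, adjusted p = 0.0027), metallothioneins and metal transport 7 of 11 higher and 1 lower (1.37, adjusted p = 0.00414) and plasma proteins 12 of 32 higher and 1 lower (0.54, adjusted p = 0.00923). All 13 mitochondrially encoded transcripts were lower (median −1.58, adjusted p = 3.29e-06), as were 15 of 24 YAP targets (−0.47, adjusted p = 0.00324).

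Of the 35 splits of each pair of groups, 1, the real one, was as large. The real split gave 2035 genes and the highest of the others 1 for BRM against NS, 1582 and 0 for double against BRG1, 2787 and 980 for double against BRM, 3284 and 1462 for BRG1 against NS, the latter from libraries 1 and 2 against 3 and 4, 3165 and 2 for double against NS and 4957 and 2253 for BRG1 against BRM. Only 18 splits of each, the real one included, spread the sets as evenly as the real one, too few for a share under 0.05, and the highest other among these gave 1, 0, 980, 0, 1 and 2253 genes in that order. In the last 3, taken as paired by number (not shown apart from the sets), 8 splits part as many pairs, with at most 0, 0 and 2253 genes. The others keep pairs together. Genes called in both singles numbered 311 in the same and 427 in opposite directions. The other splits gave at most 0 and 0 (1 of 100 as large). No other split called genes in both comparisons, so this does not test the overlap, for which independent lists would share 231 and 226. For the numbers of lists called chance cannot be excluded. They were 21 for BRG1 (highest other 25, 5 of 35 splits as large) and 14 for BRM (15, 4 of 35). For the double knockdown they were 17 (21, 8 of 35). The splits do not decide on the 10 interaction lists (24, 57 of 100).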
